A study of Caenorhabditis elegans with 4 samples.

How the data were processed

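Chromatin from Caenorhabditis elegans adults carrying fem-2(b245) was immunoprecipitated with a rabbit polyclonal antibody against ASH-2 and sequenced, with sonicated input DNA as the companion sample. The labels describe 4 samples, 2 of ASH-2 ChIP and 2 of input. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 minutes and sonicated, and 5 µg of affinity-purified antibody was used for each ChIP. Libraries were made from ChIP DNA and from 10 ng of input, per the labels' protocols. The worms are labelled as hermaphrodite young adults with a germline, whereas the growth protocol in the labels speaks of gravid adults; the labels' wording was kept. The series' design text gives a temperature of 20 degrees Celsius.

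The files analysed were 3 peak lists in which each peak has a chromosome, a start, an end and a score. One list belongs to ChIP replicate 1, one to ChIP replicate 2, and the other names no sample and is called the series list here. Per the file headers, all lists use the WormBase WS220 build, and the source column of the deposited lists names MACS for the replicate lists and MACS v2 for the series list. The submitters' processing notes name BWA and ce10. The parameters of the peak calls, the control used for each, and whether and how reads of the replicates were combined for the series list are not given in the sources used here. The score of each peak was deposited by the authors without naming its type. It ran from 50.3 to 3100 in replicate 1, from 50.1 to 3220.27 in replicate 2 and from 1.30 to 83.58 in the series list. In replicate 2, 96 peaks carried exactly 3100, and in replicate 1, 9 peaks did, so the scores at the top of those lists are tied. Scores were therefore used only to rank or filter peaks within 1 list, with ties broken by position. No values were analysed here for the input samples, so no enrichment over input was computed. The lists hold no read counts, so sequencing depth is unknown, and the intervals given for shares of peaks are 95% Wilson intervals that cover counting error only.

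Overlap was counted with a minimum of 1 bp. The overlap expected by position alone was taken from 1000 circular shifts of one list along each chromosome, which keeps peak widths, spacing and chromosome totals, with a one-sided permutation p whose smallest value is 0.001. Such a p describes the lists compared, since each replicate gives 1 list. Peak density was counted in bins of 1 Mb by peak midpoint. Each chromosome was taken to end at the last base covered by a peak in any of the 3 lists, which gave 99.9 Mb of nuclear genome in 103 bins. The centre of a chromosome was its middle 50% and the arms were the outer 25% at each end; bins were assigned by their midpoint, and shares of peaks by the midpoint of each peak. Ratios of density were tested with 100000 two-sided permutations of the labels over bins, within chromosomes for centres against arms, and the smallest p these can give is 1e-05. Bins rather than peaks were permuted because neighbouring peaks are not independent; adjacent bins are not independent either. Intervals for densities and their ratios are 95% bootstrap intervals from 10000 draws of bins. Shares were compared with Fisher's exact test, two-sided. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.

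The functions were tested on simulated lists. Of 50 simulated lists of 3009 peaks with an X to autosome ratio of 0.5 and a centre to arm ratio of 0.4, all 50 passed the threshold of 0.05 for each ratio, with mean recovered ratios of 0.507 and 0.405. With both ratios set to 1, 2 of 50 lists of that size passed for the X ratio and 1 of 50 for the centre ratio. For 50 lists of 379 peaks with ratios of 1 the counts were 3 and 2, and for 50 lists of 1901 peaks they were 6 and 0. Simulated peaks were placed independently of each other, whereas the peaks of the data are clustered. These counts therefore do not give the rate of false calls for clustered lists. A simulated list that copied 60% of its peaks from another gave 60.7% overlap.

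The tests of overlap between the lists, of overlap by score, of the X to autosome ratio and of the centre to arm ratio, the rule for naming sites and the first set of alternatives were fixed before the data were examined. Other tests were chosen after seeing the data, and the text says so where their values are given. The sites named are the 15 highest-scoring peaks of the series list that a peak of each replicate overlaps. The rule would also have named genes, but the gene table at hand follows another assembly, WBcel235, and no sequence of the WS220 build was used here. Peaks were therefore not assigned to genes. 4 planned results that need annotation or sequence of the same build were not run: peaks at gene 5′ ends, fixed gene lists, base composition and tRNA genes. The gene table served only to count protein-coding genes per chromosome. The alternatives fixed beforehand were each replicate list in place of the series list, a stricter score, peaks found in both replicates, merged neighbours, other overlap rules, other bin sizes and another definition of the centre. Others were added after seeing the data and are named as added.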

Results

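ASH-2 is a subunit of the COMPASS-type complexes that methylate histone H3 at lysine 4, a mark of active promoters, and fem-2 encodes a protein phosphatase required for male development and for spermatogenesis. ChIP-seq for ASH-2 was carried out on 2 samples of fem-2(b245) adults, each with an input sample. The data analysed were the peaks called for each ChIP replicate and a list for the whole series. Replicate 1 had 379 peaks, replicate 2 had 1901 and the series list had 3009. All positions are in the WormBase WS220 build. The control against which each list was called is not given in the sources used here, and replicate 2, unlike replicate 1, includes peaks at the first bases of 6 of 6 nuclear chromosomes and over the mitochondrial genome. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

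The replicates marked many of the same places, but with very different peak widths. Peaks in replicate 1 had a median width of 1899 bp and none was narrower than 1031 bp, whereas the median in replicate 2 was 335 bp with a minimum of 108 bp. The peaks of replicate 1 covered 916 kb of the nuclear genome and those of replicate 2 covered 1343 kb, so the count differed far more than the covered length. The series list had the narrowest peaks, with a median of 244 bp, and covered 1394 kb, or 1.40% of the nuclear span. Adjacent peaks lay less than 1 kb apart in 36.3% of cases in the series list and 35.5% in replicate 2, against 7.24% in replicate 1.

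To find how far the replicates shared sites, the positions of their peaks were compared. Of the 379 peaks of replicate 1, 244 were overlapped by a peak of replicate 2, or 64.4% (95% Wilson interval 59.4 to 69.0%). Circular shifts gave 4.43% on average and 10.6% at most, so the observed overlap was 14.5 times the chance value (permutation p = 0.001, one-sided, the smallest the 1000 shifts can give). In the other direction, 406 of the 1900 nuclear peaks of replicate 2 were overlapped by replicate 1, or 21.4% (19.6 to 23.3%), against 1.21% after shifting (permutation p = 0.001). The shared sites were mostly the strongest. In the quartile of replicate 2 with the highest scores, 227 of 476 peaks, 47.7% (43.2 to 52.2%), were overlapped by replicate 1. The share was 16.4% in the next quartile, 13.1% in the one after and 8.21% (6.06 to 11.03%) in the lowest. The odds of overlap differed 10.2 times between the top and bottom quartiles (Fisher's exact test, two-sided, p = 1e-44, with peaks treated as independent). Peaks of the top quartile were also wider, with a median of 1126 bp against 212 bp in the bottom quartile. With each list cut to the 50% of its peaks with the higher scores, 79.5% of replicate 1 peaks and 24.5% of replicate 2 peaks were overlapped. With replicate 2 cut to its top peaks, as many as replicate 1 has, 41.7% of replicate 1 peaks and 52.1% of the replicate 2 peaks kept were overlapped.

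The series list was then set against its replicates. Of the peaks of replicate 1, 378 of 379 were overlapped by a series peak (99.7%), whereas 1109 of 1901 peaks of replicate 2 were (58.3%, 56.1 to 60.5%). Replicate 1 peaks are wider and so easier to overlap, and no shifted expectation was computed for these shares. By score quartile of replicate 2, 94.5% of the top and 28.6% of the bottom quartile were overlapped by the series list. The 792 replicate 2 peaks missing from the series list had a median score of 75.7 and a median width of 268 bp, against 195 and 442 bp for those it held. All 102 replicate 2 peaks with a score of 3100 or more were in the series list. Seen from the series list, 318 of 3009 peaks (10.6%, 9.52 to 11.7%) were overlapped by both replicates. A further 332 (11.03%) were overlapped by replicate 1 only and 783 (26.02%) by replicate 2 only. Several series peaks can lie in 1 replicate peak: 650 series peaks were overlapped by replicate 1, against the 378 replicate 1 peaks given above. The 332 are therefore not as many separate sites of replicate 1. The largest class, 1576 peaks or 52.4% (50.6 to 54.2%), was overlapped by neither. Peaks overlapped by both replicates were broad and strong, with a median width of 1082 bp and a median score of 16.8. Those overlapped by neither had medians of 200 bp and 4.04, and the highest score among them was 15.8. Counting peaks within 500 bp as shared lowered the share with no replicate peak to 47.5%.

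**Figure D1:**
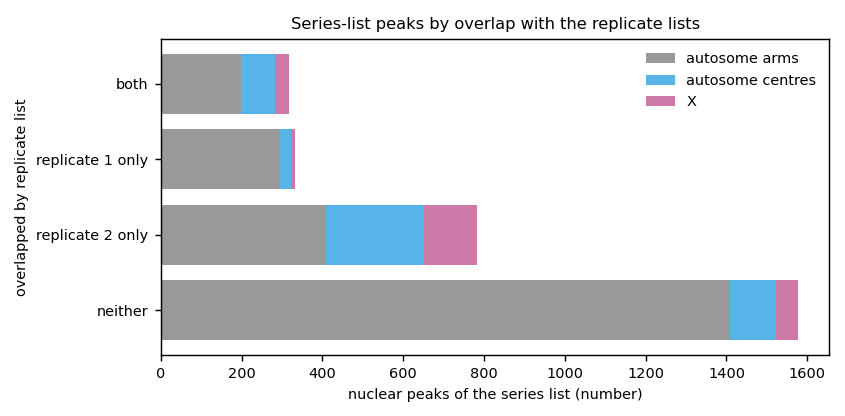
Number of nuclear peaks of the series list by whether a peak of replicate 1, of replicate 2, of both or of neither overlaps them (vertical axis), divided by colour into autosome arms, autosome centres and the X chromosome. The class with no replicate peak is the largest, with 1576 peaks, of which 1409 lie on autosome arms.

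Along the chromosomes, ASH-2 peaks were concentrated on the autosome arms. In C. elegans the arms, the outer portions of each autosome, are rich in repeats and recombination, while the gene-dense centres hold most broadly expressed genes. The series list had 55.5 peaks per Mb on the arms (bootstrap 95% interval 44.9 to 66.6) and 11.9 per Mb in the centres (9.15 to 14.9), a centre to arm ratio of 0.215 (0.156 to 0.291; permutation p = 1e-05, the smallest possible). The centre was the sparser part on 5 of 5 autosomes, with ratios from 0.164 on chromosome III to 0.275 on chromosome IV. Both replicates showed the same direction on all 5 autosomes. The ratio was 0.2497 (0.161 to 0.370) in replicate 1 and 0.513 (0.387 to 0.663) in replicate 2 (permutation p = 1e-05 in each), a mean of 0.381 ± 0.186 (SD, n = 2). The size of the arm excess thus depended on the list. Arm density was 4.66 times centre density in the series list and 1.95 times in replicate 2. Of autosomal peaks, 20.2% (16.3 to 24.7%) lay in centres in replicate 1 and 33.4% (31.2 to 35.7%) in replicate 2. The peaks that both replicates overlapped kept the direction, with a ratio of 0.439 (permutation p = 0.00089), as did base pairs covered by the series list in place of peak counts, a setting added after seeing the data, with a ratio of 0.367 (permutation p = 1e-05).

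**Figure D2:**
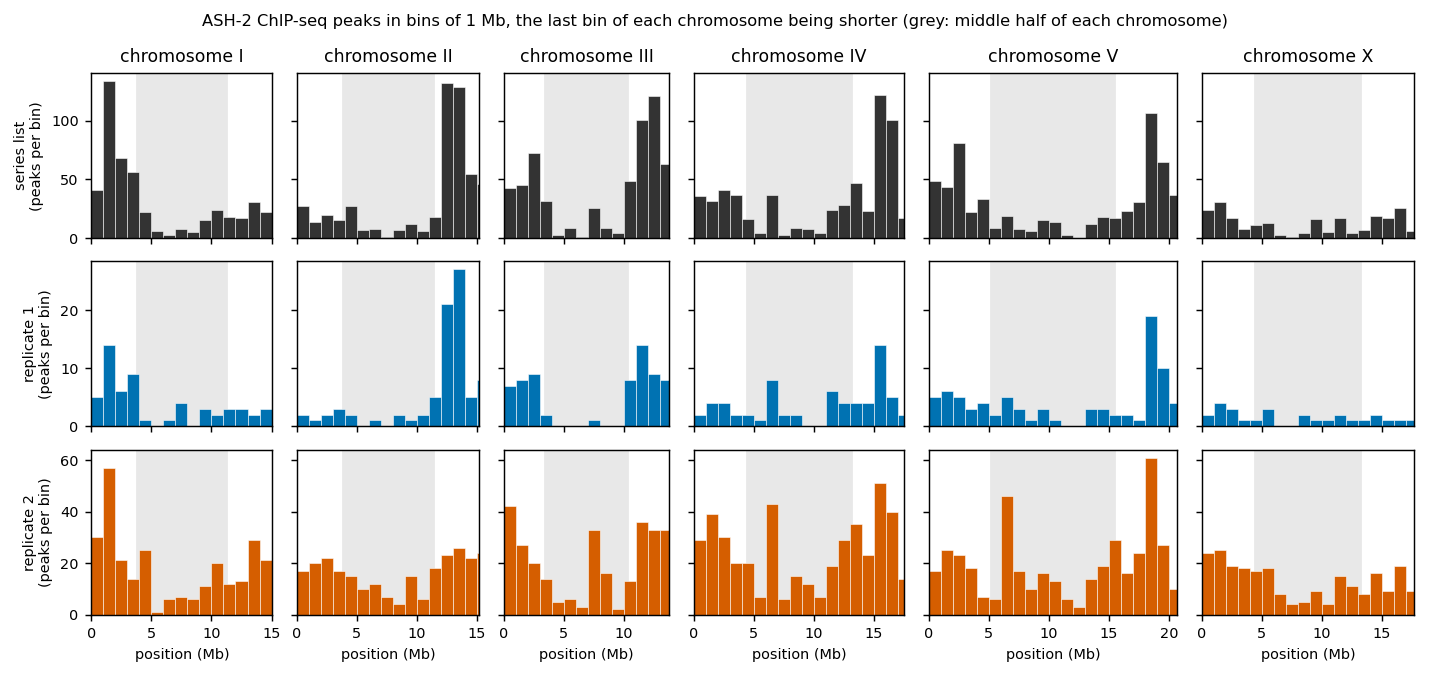
Number of ASH-2 peaks in bins of 1 Mb (vertical axis, a separate scale for each list) along the 6 nuclear chromosomes (horizontal axis, Mb) for the series list, replicate 1 and replicate 2, with the middle 50% of each chromosome shaded grey. The tallest bins lie outside the grey areas, such as chromosome I from 1 to 2 Mb with 134 peaks in the series list, 14 in replicate 1 and 57 in replicate 2.

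Peaks were also uneven along the arms, in counts chosen after seeing the data. The 8 fullest bins of the series list covered 8.01% of the nuclear span and held 947 peaks, or 31.5%. A high share in that list follows from picking its fullest bins. The centre to arm ratio without them was not computed. These 8 bins lay on 5 of 5 autosomes and all 8 were on arms. The same bins held 32.5% of replicate 1 peaks and 17.2% of replicate 2 peaks. The fullest ran from 1000001 to 2000000 on chromosome I, with 134 series peaks, 14 in replicate 1 and 57 in replicate 2. On the right arm of chromosome II, the bins starting at 12000001 and 13000001 held 132 and 129 series peaks. These were the fullest bins of replicate 1, with 21 and 27 peaks, but ranked 29 and 22 in replicate 2, with 23 and 26. On chromosome V, the bin from 18000001 to 19000000 held 107 series peaks and 61 in replicate 2, the most of any bin there. The short last bin of chromosome II, from 15000001 to 15189226, held 46 series peaks, 8 in replicate 1 and 24 in replicate 2. Centres had isolated full bins as well. The bin from 6000001 to 7000000 on chromosome IV held 37 series peaks, 8 in replicate 1 and 43 in replicate 2. On chromosome V, the bin with the same coordinates held 19 series peaks, 5 in replicate 1 and 46 in replicate 2, the most of any centre bin there. The bin from 7000001 to 8000000 on chromosome III held 26 in the series list and 33 in replicate 2 but 1 in replicate 1.

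The X chromosome carried fewer peaks than the autosomes. In C. elegans germ cells the X is transcribed little, and genes with germline expression are under-represented on it, so the X is a natural comparison in animals with a germline. The series list had 12.9 peaks per Mb on the X (bootstrap 95% interval 9.21 to 16.9) and 33.8 per Mb on the autosomes (26.8 to 41.4), a ratio of 0.383 (0.256 to 0.547; permutation p = 0.00099). The ratio was 0.357 (0.235 to 0.525) in replicate 1 (permutation p = 0.00126) and 0.666 (0.506 to 0.852) in replicate 2 (permutation p = 0.0179), a mean of 0.511 ± 0.219 (SD, n = 2). Replicate 2 alone again moved the value by over 1.5 times. The X was also compared with each part of the autosomes, in tests chosen after seeing the data. Against autosome centres the whole X had a density ratio of 1.09 (0.727 to 1.57) in the series list, 0.894 (0.569 to 1.41) in replicate 1 and 0.983 (0.715 to 1.35) in replicate 2, and none of these ratios passed the threshold against 1 (permutation p = 0.701, 0.689 and 0.942). Against autosome arms the ratio was 0.233 in the series list and 0.223 in replicate 1 (permutation p = 1e-05 each), and 0.504 in replicate 2 (permutation p = 2e-05). The X had its own sparser middle, with 8.22 peaks per Mb in the middle 50% and 17.8 in the outer parts. The middle of the X had 0.689 times the density of autosome centres in the series list, 0.716 times in replicate 1 and 0.739 times in replicate 2, below 1 in every list without passing the threshold (permutation p = 0.218, 0.414 and 0.295). Over the 318 series peaks found in both replicates the ratio of the whole X to the whole autosomes was 0.575 and no longer passed the threshold (permutation p = 0.0758), with 35 peaks on the X.

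**Figure D3:**
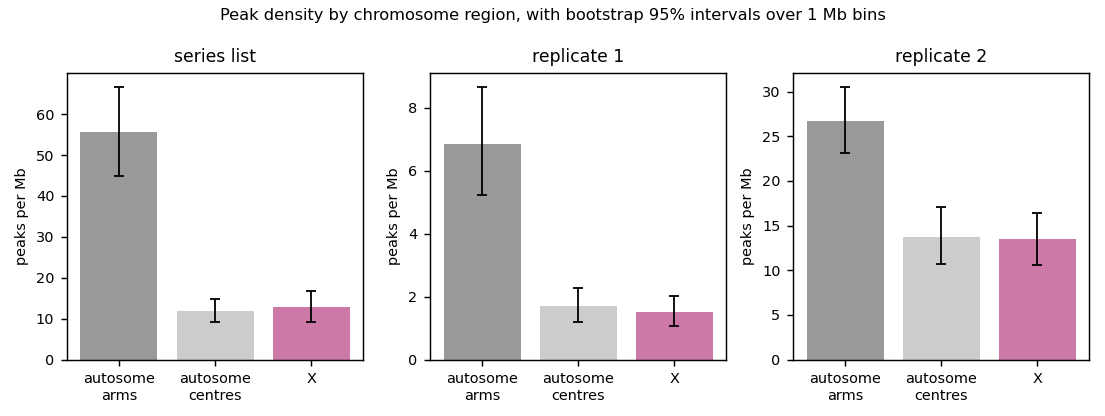
Peaks per Mb on autosome arms, autosome centres and the X chromosome for each peak list; bars are densities and error bars bootstrap 95% intervals over bins of 1 Mb. Arms stand above centres and the X in every list (55.5, 11.9 and 12.9 per Mb in the series list), and the intervals of centres and X overlap.

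The classes of series peaks differed in where they lay, a comparison chosen after seeing the data. Of the autosomal peaks overlapped by neither replicate, 7.42% (6.21 to 8.85%) were in centres, and of those overlapped by replicate 1 only, 8.36% (5.81 to 11.9%). Centres held 37.3% (33.7 to 41.1%) of those overlapped by replicate 2 only and 30.04% (24.99 to 35.6%) of those overlapped by both. The X held 3.43% of the class with no replicate peak, 2.71% of the replicate 1 only class, 16.8% of the replicate 2 only class and 11.01% of the class found in both. The class with no replicate peak and the replicate 2 only class differed in both shares (Fisher's exact test, p = 4e-61 for centres and p = 1.4e-27 for the X, with peaks treated as independent). Part of this follows from how the classes are defined. Replicate 2 itself had 33.4% of its autosomal peaks in centres, against 16.8% in the series list, and series peaks that overlap it share its positions.

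The strongest sites found in both replicates are given by position. The highest score, 83.58, belonged to a peak of 2295 bp on chromosome IV from 13921967 to 13924261, on the right arm. It was followed by a peak of 9256 bp on the left arm of chromosome II, from 3159380 to 3168635, with a score of 74.02, which replicate 1 called as 1 peak of 9954 bp and replicate 2 as 1 peak of 9181 bp. Next came chromosome IV from 5464625 to 5467188, in the centre, with a score of 71.86. The fourth, on chromosome III from 10505924 to 10506573, was only 650 bp wide and scored 66.23. The one site of the 15 on the X ran from 142771 to 143692, near the left end, with a score of 56.29. Of the 15 sites, 9 were on autosome arms and 5 in autosome centres. Chromosome II had 6 of them, IV had 4, V had 3, III had 1 and I had 0. Their median width was 1239 bp. In replicate 2, 12 of the 15 had a score of 3100 or more, a range in which 96 of 102 peaks are tied at exactly 3100.

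Broad regions, examined after seeing the data, were shared between replicates in part. The series list had 23 nuclear peaks of 5 kb or more, of which 23 were overlapped by replicate 2 and 16 by replicate 1. Of these 23, 11 were on autosome arms, 8 in centres and 4 on the X. Of the 21 such peaks in replicate 1, replicate 2 overlapped 20, against 2.11 on average after circular shifts, and of the 29 in replicate 2, replicate 1 overlapped 13, against 0.959 (permutation p = 0.001 each, the smallest possible). The widest series peak, 12340 bp on chromosome II from 9812457 to 9824796, was overlapped by replicate 2 and not by replicate 1. The same held for the next, 12129 bp on chromosome V from 6077153 to 6089281. A peak of 9060 bp on chromosome V from 7915978 to 7925037 and one of 7749 bp on chromosome III from 13074524 to 13082272 were overlapped by both.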

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

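Settings described as added were chosen after seeing the data. The centre to arm ratio kept its direction and passed the threshold under all 15 alternatives, 7 of them added, from 0.199 (chromosome IV left out, added) to 0.513, and with a single replicate list in place of the series list it ranged from 0.2497 to 0.513. The X to autosome ratio stayed below 1 under all 15, 7 of them added, and passed under 14, from 0.345 to 0.666, with a range of 0.357 to 0.666 for single replicate lists. The exception was the restriction to peaks overlapped by both replicates, with a ratio of 0.575 and a permutation p of 0.0758 over 318 peaks; the cause was not tested. Counted per protein-coding gene, the X to autosome ratio was 0.520. Its p did not come from permuting bins, since it lay below the smallest value these can give. That pass is therefore not comparable with the other passes. In base pairs covered, an added setting, the X to autosome ratio was 0.499 and the centre to arm ratio was 0.367. Leaving out each autosome in turn, also added, gave 0.368 to 0.403 for the X and 0.199 to 0.229 for the centres. Overlap between the replicates exceeded the shifted lists under all 6 alternatives in each direction, of which the midpoint rule and local shifts were added. The shares ran from 41.7 to 79.5% of replicate 1 peaks and from 20.2 (midpoint rule, added) to 52.1% of replicate 2 peaks, and the odds ratio between score quartiles ranged from 7.70 to 10.6. Shares of the series list stayed within their intervals when 50% of the shorter peak had to overlap, at 21.1% for replicate 1, 35.6% for replicate 2, 10.2% for both and 53.6% for neither, and moved beyond them under the next 2 settings. Counting within 500 bp gave 24.6% with a replicate 1 peak, 41.3% with a replicate 2 peak, 13.4% with both and 47.5% with neither. The 50% of the list with the higher scores gave 33.8%, 50.4%, 19.9% and 35.6%. Requiring the midpoint of the series peak inside the replicate peak, an added setting, moved 2 of the 4 shares, to 34.2% for replicate 2 and 9.37% for both. No paired analysis was possible because no values of the input samples were analysed and each replicate gives a single list. The alternatives for gene 5′ ends, gene lists, base composition and tRNA genes were not run, since no annotation or sequence of the WS220 build was used here. The depth of the libraries is unknown, so whether the shorter list of replicate 1 comes from fewer reads cannot be examined.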

Other observations

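The ratio over peaks found in both replicates was planned before the data were examined. It was planned as an alternative setting, and its use to test an explanation was not among the tests fixed then. The test of distance to replicate peaks was fixed before its result was seen. The other tests in this part were chosen after seeing the data. Replicate 2 had peaks at high-copy parts of the genome that replicate 1 did not. On 6 of 6 nuclear chromosomes its first peak began within the first 5 bases of the sequence, where the telomere lies, with widths from 214 bp on chromosome III to 518 bp on chromosome I. Replicate 1 had 0 such peaks, its earliest start being 83299, and the series list had 0, its earliest being 1923. The last peak of replicate 2 on chromosome I ran from 15060222 to 15071348 with a score of 3100, at the end that carries the ribosomal RNA gene array; the last series peak there ran from 15068767 to 15071169 with a score of 3.17, and the last replicate 1 peak ended at 14687827. Nearly the whole mitochondrial genome was 1 peak in replicate 2, from 2 to 13448 with a score of 3100, and in the series list, from 1 to 13296 with a score of 14.5, while replicate 1 had 0 peaks there. For comparison, 68 of the 102 replicate 2 peaks that scored 3100 or more were overlapped by replicate 1 (66.7%, 95% Wilson interval 57.1 to 75.1%). Whether replicate 2 was called against the same control as replicate 1, another or none is not given in the sources used here, and this doubt applies to every value of replicate 2, its number of peaks, overlaps and ratios included.

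Across the 103 bins of 1 Mb, peak density in the series list followed both replicates, with a Spearman rho of 0.802 with replicate 1 and 0.816 with replicate 2; the replicates had a rho of 0.661 with each other (rotation of bins within chromosomes, permutation p = 0.001 each). Between the replicates the rho was 0.401 within arm bins and 0.595 within autosome centre bins. These are correlations across bins, which are not independent replicates. The series list may have been called from the same reads as the replicate lists. Its rho and p with each replicate are therefore not independent support, unlike those between the replicates. Over the 44 arm bins alone the rho was 0.806 for replicate 1 with the series list and 0.544 for replicate 2. Over the 41 autosome centre bins the values were 0.653 and 0.839.

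The first pattern examined was the excess of peaks on autosome arms. If it came from weak peaks found in one list alone, it would be gone among series peaks that both replicates overlap, but there the centre to arm ratio was 0.439 (permutation p = 0.00089). If it came from broad arm regions split into many peaks, merging peaks under 10 kb apart would remove it, but the ratio was then 0.301 (permutation p = 1e-05). The ratios of 0.439 and 0.301 each argue against their own explanation, taken alone, as the whole cause. Both lie nearer to 1 than the 0.215 of the full list. Merging under 10 kb joins more peaks wherever they are dense, however they arose, whereas merging peaks under 500 bp apart gave 0.1996. Series peaks that overlap replicate 2 share its positions, and that list had a ratio of 0.513. The 0.439 therefore does not isolate the removal of weak peaks. Among the 1505 series peaks with the higher scores, a planned setting, the ratio was 0.255 (permutation p = 1e-05), so the excess was also present there. Whether either explanation adds to the size of the excess therefore cannot be told from these values. The restriction to shared peaks and the 10 kb merging were not applied together, so their joint effect was not tested. A difference between the strain and the reference in copy number, the handling of repeats and of input by the peak caller, and ASH-2 occupancy on the arms all stay open and untested, since no input values were analysed and the series holds 1 genotype.

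The second was the 1576 series peaks that neither replicate overlapped. One candidate explanation is that they are flanks of regions the replicates also hold; 630 of them, 40.0% (95% Wilson interval 37.6 to 42.4%), lay within 5 kb of a replicate peak. That is above the 14.4% average and the 20.1% maximum of 100 circular shifts, but under the 50% set beforehand for this to account for most of them. Of the 1576 peaks, 1409 lie on autosome arms, where replicate peaks are also denser. Shifts along whole chromosomes do not keep this, so the excess over them may reflect shared arm location rather than flanks. Whether the 1576 peaks are weak sites that passed in the series call alone was not tested, since their low scores are part of the pattern itself. The settings of the calls, which differ in program between the lists, were not varied here, and no biological explanation was tested.

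The third was the lower density on the X. A candidate explanation is that the X lacks the dense arms of the autosomes: the density of the whole X, outer parts included, was 1.09 times that of the autosome centres in the series list (0.727 to 1.57), which does not exclude it. The outer parts of the X had 0.321 times the density of autosome arms in the series list (permutation p = 4e-05), 0.269 times in replicate 1 (permutation p = 5e-05) and 0.633 times in replicate 2 (permutation p = 0.00866), and the middle 50% of the X had 0.689, 0.716 and 0.739 times that of autosome centres in the same lists (permutation p = 0.218, 0.414 and 0.295), so a smaller deficit in the middle of the X is not excluded. The p-values for the X treat bins of 1 chromosome as independent and do not allow for differences between whole chromosomes. Low transcription of the X in germ cells remains a possible explanation that was not tested.

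Chromosome ends were unequal to different degrees. The most unequal in the series list were chromosome II, with 76 peaks in the left 25% and 378 in the right, and chromosome I, with 295 and 91. In replicate 1 these were 8 and 64 on chromosome II and 34 and 11 on chromosome I. In replicate 2 they were 73 and 107 on chromosome II and 120 and 76 on chromosome I. The hypothesis that peaks gather at the end with the meiotic pairing centre, taken from background knowledge as the right end of I and V and the left end of II, III, IV and X, found no support. The mean log2 ratio of that outer 25% to the opposite one was -0.91 ± 1.03 in the series list (SD, n = 6 chromosomes; exact sign-flip test, two-sided, p = 0.125). It was -0.85 ± 1.43 in replicate 1 (exact p = 0.25) and -0.058 ± 0.632 in replicate 2 (exact p = 0.875), and the pairing-centre end had more peaks on 2 of 6 chromosomes in each of the 3 lists.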
